A study of Mus musculus with 6 samples.

How the data were processed

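Gene expression was measured in mammary gland RNA from 6 female Trp53 knockout mice, 3 on a high-fat and 3 on a control diet, with 1 single-colour (Cy3) Agilent mouse array per mouse. Groups and replicate numbers follow the labels, which describe the samples as biological replicates of mice assigned to a diet at random. Per the file headers, each array was read with Agilent Feature Extraction 11.0.1.1, and the deposited scanner files hold the intensity of 44397 spots on a linear scale: a processed signal after background subtraction and detrending, and the median spot and local background signals. The deposited table of values for 30608 probes holds intensity values on a linear scale, neither logged nor centred. Set against each array's scanner values, 99.9% of its values stood in 1 ratio (within 1%) to the processed signal, close to 1 over the 75th percentile of the array, so its scale is known although no label states it. Its column medians were 0.134, 0.134 and 0.137 for high-fat replicates 1 to 3 and 0.134, 0.140 and 0.134 for control replicates 1 to 3.

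From the scanner files, control spots and spots flagged as outliers were left out, spots of 1 probe were averaged, and 111 of 39429 probes without a usable spot on every array were dropped. Each array's log2 processed signal was taken relative to its 75th percentile. Probes well above background on at least 3 of the 6 arrays were kept (28687), and for each gene the probe with the highest mean was used, leaving 23458 genes or unnamed transcripts. Of these, 4389 had several such probes, and in 1412 the probes differed in sign. The scanner files carry no gene names, so probes were named through their RefSeq accessions: 27427 of 39429 probes matched 1 symbol, and the rest kept their accession or probe identifier. Where a probe was not well above background on any array of a group, the fold is a lower bound, taken against the mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background. The processed signal is the only signal used in the main analysis. The files give median but no mean spot signals, so the normexp background (offset 50) tried as another setting was computed on the median spot signal and the median local background.

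Diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, threshold 0.05), with high-fat minus control as the coefficient and no covariates. With 3 mice against 3 an exact permutation test cannot reach 0.05, so the tests rest on limma's pooled spread. The 30 gene lists, the tests, the named-gene rule and the other settings to try were fixed before the data were examined. They were MYC targets, MYC turnover, cell cycle, p53 targets, luminal epithelium, basal and myoepithelium, milk, white adipocyte, brown adipocyte, lipogenesis, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, glycolysis, growth factors, macrophages, T and NK cells, B cells, neutrophils and mast cells, inflammation, interferon, fibroblast and matrix, endothelium, skeletal muscle, Schwann cells, keratinocytes, erythroid cells, immediate early genes, endoplasmic reticulum stress and clock. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. The correlation was also estimated within each alternative run with camera, except for lists cut to members of no other list, a test chosen after the values were seen. Named genes were, per direction, the 12 with the largest difference among genes past the threshold whose diets did not overlap, filled up by the smallest p where fewer passed; in each list up to 6 members past the test, or else the 4 with the smallest p; and Myc and Trp53. Identifiers without a gene symbol were passed over, and the text names a selection of the genes the rule allows; some of them are not reported here.

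Slide was tested as a block, as scan times coincided with slides and all scans fell on 1 day. One slide held high-fat replicates 2 and 3 with control replicate 1, so the blocked and the within-slide estimates are the same. Alternatives covered scaling, background, the filter, a floor on dim signals, the probe rule, variance settings, array weights, blocks, marker-list covariates, the deposited table of values, thresholds and leaving out each array. The methods were tested on simulated data with the real genes' means and spreads, 200 changed genes per run and independent noise. In the comparison of high-fat with control over 23458 genes, 39.7% of log2 changes of 1, 76.4% of 2 and 91.2% of 3 were called, 5.49% of calls were false, and a list shifted by 0.5 was found in 5 of 5 runs. Correlated noise between genes, as real arrays have, was not simulated.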

Results

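RNA from the mammary glands of 6 female mice lacking Trp53 was measured on 6 single-colour arrays, 1 array per mouse. From 3 weeks of age, 3 mice ate a high-fat diet and 3 a control diet. All were 8 weeks old when the glands were taken, after 5 weeks of feeding. The labels name whole glands as the source and mammary epithelial cells in the sample descriptions. Which of these was hybridised is not known, and a gland below means a sample of either kind. Of the array's 39429 probes, between 27202 and 29409 lay well above background on each array, and no probe was saturated. The 75th percentile of signal ranged from 1326 intensity units on control replicate 2 to 1973 on high-fat replicate 1. After filtering, 23458 genes or unnamed transcripts were tested. The number of arrays limits the precision. Levels below are log2 signal minus the array's 75th percentile, and differences are high-fat minus control, with n = 3 mice per diet throughout. No genome positions are given, because the array was annotated on an older mouse build than the gene table used for names.

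The first comparison asked which genes differed between the diets. Of the 4 genes past the test, all lower after the high-fat diet, 3 encode parts of the contractile and calcium-handling machinery of striated muscle. Myh3 (NM_001099635), the embryonic myosin heavy chain, fell 8.51-fold, from a level of 1.35 ± 0.23 (SD, n = 3) under control diet to -1.73 ± 0.39 (SD, n = 3). Myl4 (NM_010858), an atrial and embryonic myosin light chain, fell 4.28-fold, from 2.85 ± 0.16 to 0.75 ± 0.11 (SD, n = 3 each). Cacna1s (NM_001081023), the voltage sensor of skeletal muscle calcium release, fell 4.46-fold, from -2.17 ± 0.14 to -4.32 ± 0.16 (SD, n = 3 each). Igf2 (NM_010514), a fetal growth factor also made by differentiating muscle cells, fell 3.57-fold, from -4.66 ± 0.16 to -6.50 ± 0.06 (SD, n = 3 each). On the high-fat arrays it was well above background but dim, close to the lowest detected signal on high-fat replicate 2. With a normexp background and the 75th percentile its log2 difference was 0.13, where the median of all genes was 0.27. These 4 genes, each lower in 3 of 3 high-fat arrays than in any control array, were the ones past an adjusted p of 0.05 in limma (adjusted p = 0.039 for Myl4, Cacna1s and Igf2 and 0.044 for Myh3). In limma 0 genes passed as higher, where 1379 had higher values at an unadjusted p under 0.05.

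The next genes by p did not pass. Among those with lower values were Myom2, a protein of the sarcomere's M band (log2 difference -2.43, SE 0.21), and Tnni1, the slow troponin I (-1.98, SE 0.16). Mybph, a myosin binding protein (-1.79, SE 0.19), Hrc, a calcium-binding protein of the sarcoplasmic reticulum (-1.20, SE 0.11), and Cav3, the muscle caveolin (-1.99, SE 0.21), were close behind. Trim72, a muscle membrane repair protein, differed by -1.78 (SE 0.18), though by 0.18 with normexp and the 75th percentile. Srpk3, a muscle protein kinase, was not well above background on any high-fat array and was at least 4.21-fold lower there, while its log2 difference was 0.25 with normexp and the 75th percentile. Adjusted p for these genes ranged from 0.054 for Tnni1 to 0.091 for Cav3. Genes with higher values after the high-fat diet included Krt5, a keratin of basal epithelial cells (log2 difference 1.27, SE 0.16), and Krtdap, a product of differentiating keratinocytes (2.21, SE 0.31). Mrvi1, a smooth muscle calcium regulator (1.35, SE 0.14), Tspan2, a tetraspanin (1.30, SE 0.18), and Nuak2, a protein kinase (1.16, SE 0.15), were higher too, as were Tenm2 (1.30, SE 0.15), Serpinb10 (1.45, SE 0.19), Rflnb (1.19, SE 0.17), Scube3 (0.92, SE 0.13) and Asb2 (1.11, SE 0.15). Sv2b differed by 2.39 (SE 0.28), with 1 of 3 control arrays well above background, and Pou2af1 by 1.77 (SE 0.25). Their adjusted p ranged from 0.091 for Mrvi1 to 0.117.

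At an unadjusted p under 0.05, 3129 genes were called, where 1173 would be called on average by chance, and 1379 of them had higher and 1750 lower values after the high-fat diet. That average gives no spread for correlated genes. At the same threshold, the split of high-fat replicates 1 and 2 with control replicate 1 against the other arrays gave 5860 genes. The remaining splits that mix the diets gave 202 to 1234. In 4040 genes, or 17.2%, the 3 arrays of one diet all lay on one side of the other 3, where chance gives 10%. The arrays did not part cleanly by diet: on the first principal component, which held 46.7% of the variance, high-fat replicates 1 and 2 scored -56.0 and -50.1, control replicates 2 and 3 scored 48.8 and 49.4, and high-fat replicate 3 (7.35) and control replicate 1 (0.57) lay between them. Leaving out high-fat replicate 3 raised the count to 37 genes, all lower, and leaving out any other single array lowered it to 0 (1413 to 5425 at an unadjusted p under 0.05). The arrays lay on 3 slides, and 1 slide held both diets (high-fat replicates 2 and 3, control replicate 1). A fit with slide as a block, which takes its estimate from that slide alone, called 0 genes at an adjusted p under 0.05 and 1232 at an unadjusted p under 0.05. The 4 genes differed there by -3.20 (Myh3), -2.30 (Myl4), -2.25 (Cacna1s) and -1.99 (Igf2), with an adjusted p of 0.696 for Myl4.

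**Figure D1:**
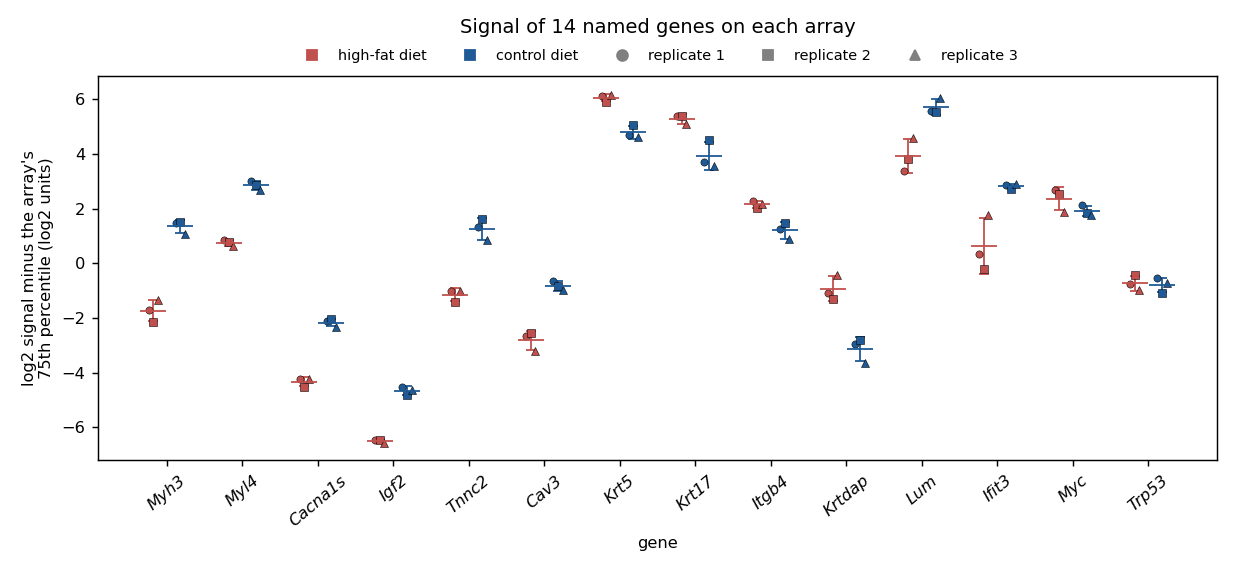
Log2 signal minus the array's 75th percentile (y axis) of 14 named genes (x axis) on each of the 6 arrays, high-fat diet in red and control diet in blue, with the marker shape giving the replicate and the bars the mean ± SD (n = 3). Myh3, Myl4, Cacna1s and Igf2 passed the test, and the other 10 did not.

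The second comparison took 30 gene lists fixed before the data were examined. With camera's preset correlation, 10 lists passed an adjusted p of 0.05, 5 higher and 5 lower after the high-fat diet. With a correlation estimated for each list, 0 passed, and the lowest adjusted p was 0.196. With an estimated correlation camera also uses the few residual degrees of freedom of so few arrays, which lowers its power. For the brown adipocyte list, whose estimate lay below the preset, camera's unadjusted p still rose from 0.0018 to 0.027. Not passing this test is therefore not evidence that a list did not shift. Among the called lists the estimate ran from -0.011 for brown adipocyte to 0.79 for interferon genes, with 0.57 for MYC targets, against the preset 0.01. Where it is high, the genes of a list move together, and a count of genes with the same sign is not a count of independent observations. With fry, which asks whether a list's genes move one way without comparing them with other genes, 2 passed: the skeletal muscle list (adjusted p = 0.012) and the brown adipocyte list (adjusted p = 0.033).

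The skeletal muscle list was lower after the high-fat diet (adjusted p = 6.3e-12 with the preset correlation, adjusted p = 0.196 with an estimated correlation). Its median log2 difference was -0.94 over 26 measured genes, 21 of them negative, and no member passed over all genes, while 17 passed as lower and 0 as higher when adjusted over the list alone. Troponins and a fast light chain led it: Myl1 differed by -3.16 (SE 0.36), Tnnc2 by -2.40 (SE 0.23), Tnnt3 by -2.20 (SE 0.23) and Tnni1 by -1.98. The list's mean was -3.73 ± 0.08 on the high-fat and -2.78 ± 0.14 on the control arrays (SD, n = 3 each), with the groups apart. Within the shared slide the median difference was -0.95. With normexp and the 75th percentile the median was 0.13, which lay -0.14 from the median of all genes, and the list still tested as lower (adjusted p = 0.0017).

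Basal and myoepithelial markers were higher after the high-fat diet (adjusted p = 1.5e-09, adjusted p = 0.267 with an estimated correlation). The median was 0.74 over 25 genes, 22 of them positive, with 0 past the test over all genes and 11 higher and 0 lower when adjusted over the list alone. The members with the smallest p were Krt5, Myh11, the smooth muscle myosin (1.21, SE 0.18), Itgb4, the hemidesmosome integrin (0.96, SE 0.18), and Krt17 (1.36, SE 0.27). Some keratinocyte markers were higher as well: Krtdap (2.21), Dmkn (1.46, SE 0.27) and Krt15 (0.65, SE 0.21), while Serpinb12 was lower (-0.92, SE 0.25). Of these, Krt15 was well above background on 2 of 3 control arrays and Serpinb12 on 2 of 3 high-fat arrays. The keratinocyte list did not pass with the preset correlation (median 0.12, adjusted p = 0.164). The mean of the basal and myoepithelial list was 1.89 ± 0.19 under high-fat and 1.22 ± 0.12 under control diet (SD, n = 3 each), and its median within the shared slide was 0.85.

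Luminal epithelial markers were also higher (adjusted p = 4.5e-04, adjusted p = 0.690 with an estimated correlation). The median was 0.53, and 27 of 32 genes were positive. Over all genes, and when adjusted over the list alone, 0 passed. Esr1, the oestrogen receptor, differed by 0.75 (SE 0.18), Wnt4 by 1.34 (SE 0.42), Cd24a by 0.65 (SE 0.24) and Epcam by 0.79 (SE 0.30). High-fat replicate 3 had a list mean of 0.36, within the control range of 0.14 to 0.66, and within the shared slide the median difference was 0.00332 (adjusted p = 0.821).

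Fibroblast and matrix genes were lower (adjusted p = 2.2e-05, adjusted p = 0.690 with an estimated correlation). The median was -0.61, and 30 of 34 genes were negative, with 0 past the test over all genes and 3 lower when adjusted over the list alone. Lum and Dcn, small proteoglycans of the collagen matrix, differed by -1.80 (SE 0.33) and -1.62 (SE 0.33), and Pdgfra, a receptor of fibroblasts, by -1.66 (SE 0.37). The list's mean on high-fat replicate 3 was 3.47, close to the 3.66 and 3.73 of control replicates 2 and 3, and within the shared slide the median was 0.091 (adjusted p = 0.821), opposite to the pooled direction. Without high-fat replicate 3 the median was -1.04.

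Interferon-induced genes were lower (adjusted p = 9.0e-11, adjusted p = 0.661 with an estimated correlation). All 28 measured genes had negative differences, with a median of -1.07, and 0 passed over all genes or when adjusted over the list alone. Ifit3, an interferon-induced antiviral protein, differed by -2.19 (SE 0.49), Cxcl10, a T-cell attracting chemokine, by -2.40 (SE 0.61), Stat2 by -1.31 (SE 0.35) and Gbp2 by -0.89 (SE 0.23). The list's mean was 0.81 and 0.21 on high-fat replicates 1 and 2 but 1.92 on high-fat replicate 3, next to 1.94 on control replicate 1. Within the shared slide the median was -0.62, but there the list's mean differed from that of control replicate 1 by -1.73 on high-fat replicate 2 and by -0.022 on high-fat replicate 3. Without high-fat replicate 2 the median was -0.70. The inflammation list was lower as well (adjusted p = 0.0034, adjusted p = 0.637 with an estimated correlation), with a median of -0.35 and a mean of -0.74 over 33 genes and 9 lower and 2 higher when adjusted over the list alone. The monocyte chemokines Ccl2 and Ccl7 differed by -0.86 (SE 0.16) and -0.96 (SE 0.18) and the adhesion molecule Vcam1 by -1.53 (SE 0.32), while Il1rn, the interleukin-1 receptor antagonist, differed by 0.76 (SE 0.11). On its other probe Vcam1 differed by -0.42. Without control replicate 1 the inflammation list no longer passed (median -0.50, adjusted p = 0.183), and its median was -0.67 without high-fat replicate 2 and -0.67 without control replicate 2. Within the shared slide it was -0.55 (adjusted p = 4.1e-04, adjusted p = 0.634 with an estimated correlation).

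**Figure D2:**
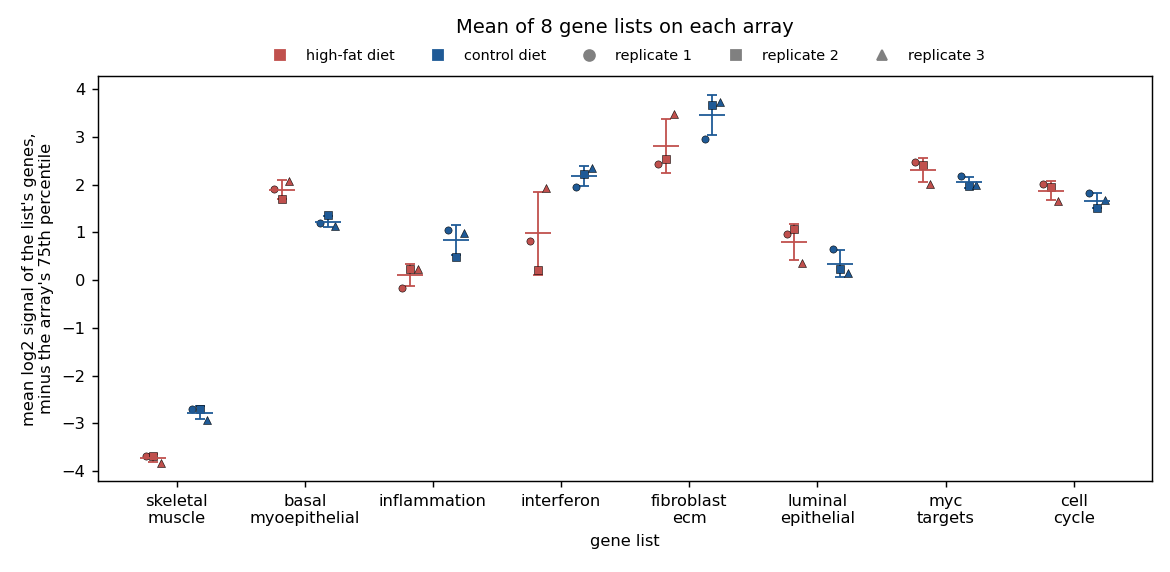
Mean log2 signal minus the array's 75th percentile (y axis) over the genes of 8 lists (x axis) on each of the 6 arrays, high-fat diet in red and control diet in blue, with the marker shape giving the replicate and the bars the mean ± SD (n = 3). The diets were apart for the skeletal muscle, basal, inflammation and interferon lists, the last by 0.022 between high-fat replicate 3 and control replicate 1, while high-fat replicate 3 lay within the control range for the luminal, fibroblast, MYC target and cell cycle lists.

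The series title names MYC stabilization in the gland's epithelium, so genes activated by MYC were the list it points to. They were higher after the high-fat diet with the preset correlation (adjusted p = 2.4e-05), but not with an estimated one (adjusted p = 0.690 with an estimated correlation). The median log2 difference was 0.28, and 51 of 56 genes were positive. None passed over all genes or when adjusted over the list alone, and 5 had higher and 1 lower values at an unadjusted p under 0.05. Las1l and Nop16, factors of ribosome assembly, differed by 0.74 (SE 0.23) and 0.60 (SE 0.21), the hexokinase Hk2 by 0.39 (SE 0.14), and Odc1, the rate-limiting enzyme of polyamine synthesis, by -0.67 (SE 0.16). The list's means of 2.48, 2.40 and 2.02 on high-fat replicates 1 to 3 stood beside luminal list means of 0.96, 1.08 and 0.36, and its means of 2.18, 1.97 and 2.00 on control replicates 1 to 3 beside 0.66, 0.23 and 0.14. Leaving out high-fat replicate 1 put the median at 0.14 and leaving out high-fat replicate 3 at 0.44. Within the shared slide the median was 0.025 (adjusted p = 0.821), and with normexp and the 75th percentile it was 0.19, -0.08 from the median of all genes.

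The Myc transcript itself (NM_010849) had a level of 2.36 ± 0.41 under high-fat and 1.91 ± 0.19 under control diet (SD, n = 3 each), a difference of 0.45 (SE 0.23, adjusted p = 0.423). That difference was 0.30 without high-fat replicate 1, 0.69 without high-fat replicate 3 and 0.081 within the shared slide. Genes acting on MYC protein turnover showed no shift as a list, with a median of 0.03, a mean of -0.01 and an adjusted p of 0.955 over 34 genes. Of its members, the deubiquitinases Usp28 and Usp22 differed by -0.46 (SE 0.15) and 0.46 (SE 0.15), and Fbxw7, the ubiquitin ligase subunit that recognises MYC, by 0.35 (SE 0.15). Arrays of RNA do not measure MYC protein. The Trp53 probe (NM_011640) was well above background on all 6 arrays, at -0.73 ± 0.27 under high-fat and -0.79 ± 0.26 under control diet (SD, n = 3 each), a difference of 0.06 (SE 0.20, adjusted p = 0.899). Whether that probe lies in the deleted part of the gene is not known, and no wild-type mice were measured here, so its signal checks nothing about the knockout. The p53 target list did not pass (median 0.11, adjusted p = 0.168), though it passed as higher in 2 alternatives, the luminal covariate (adjusted p = 0.031) and that without high-fat replicate 1 (median 0.15, adjusted p = 0.041, adjusted p = 0.716 with an estimated correlation). Perp, a desmosome protein, differed by 0.92 (SE 0.19) and the death receptor Fas by -1.31 (SE 0.41).

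The DNA replication and mitosis list was higher with the preset correlation (adjusted p = 4.5e-04, adjusted p = 0.690 with an estimated correlation). Its median was 0.19 and 37 of 40 genes were positive, with 0 past the test over all genes or when adjusted over the list alone. Ndc80, of the kinetochore, differed by 0.47 (SE 0.16) and Nusap1, of the spindle, by 0.33 (SE 0.12). Without control replicate 2 the list did not pass (median 0.11, adjusted p = 0.070), without high-fat replicate 1 its median was 0.12, within the shared slide its median was -0.022 (adjusted p = 0.613), and with normexp and the 75th percentile it was 0.08, -0.19 from the median of all genes. Cholesterol synthesis genes were higher likewise (adjusted p = 0.0045, adjusted p = 0.753 with an estimated correlation), with a median of 0.21, 21 of 26 genes positive and 0 past the test on either count. Stard4, a sterol transport protein, differed by 0.37 (SE 0.17), and Insig1, a sterol-responsive regulator of the pathway, by 0.41 (SE 0.21). Without control replicate 2 its median was 0.13 (adjusted p = 0.285), within the shared slide its median was -0.062 (adjusted p = 0.150), and with normexp and the 75th percentile it was 0.06, -0.20 from the median of all genes.

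Brown adipocyte markers were lower (adjusted p = 0.0053, adjusted p = 0.267 with an estimated correlation), with a median of -0.34 over 21 genes, 0 past the test over all genes and 3 lower when adjusted over the list alone. Cox8b, a cytochrome oxidase subunit of muscle and brown fat, differed by -1.91 (SE 0.33), Fabp3, the heart and muscle fatty acid binding protein, by -0.85 (SE 0.25), and Zic1 by -1.15 (SE 0.27). On their other probes Fabp3 differed by -1.36 and Zic1 by -0.09. Without control replicate 1 the list did not pass (median -0.16, adjusted p = 0.091), without high-fat replicate 1 its median was -0.53, and within the shared slide it was -0.51 (adjusted p = 0.0011, adjusted p = 0.634 with an estimated correlation). With normexp and the 75th percentile the median was 0.16, -0.10 from that of all genes. White adipocyte markers did not pass (median 0.12, adjusted p = 0.372), but within the shared slide they passed as higher, with a median of 0.11 (adjusted p = 0.026, adjusted p = 0.634 with an estimated correlation). Leaving out 1 array moved the white adipocyte median between 0.051, without high-fat replicate 2, and 0.20, without control replicate 3. Among the white adipocyte markers Cfd, the adipsin gene, differed by 1.78 (SE 0.27), Pparg, the regulator of adipocyte differentiation, by -1.09 (SE 0.25), and Adipoq by 1.04 (SE 0.22), with 2 of 3 control arrays well above background.

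Of the other metabolic lists, fatty acid oxidation (median -0.12, adjusted p = 0.217), glycolysis (-0.16, adjusted p = 0.135), lipogenesis (0.02, adjusted p = 0.955) and oxidative phosphorylation (0.00428, adjusted p = 0.955) did not pass. Within the first, Angptl4, a fasting-induced inhibitor of lipoprotein lipase, differed by -2.19 (SE 0.40) and Cpt1a, the carnitine palmitoyltransferase of mitochondrial fat import, by -1.02 (SE 0.22), and 2 members were lower when adjusted over that list alone. The glycolysis list passed as lower in 7 of 26 alternatives, among them those without high-fat replicate 2 (adjusted p = 0.033) or control replicate 1 (adjusted p = 0.049), and as higher in 1, the epithelial covariate (median 0.27, adjusted p = 0.0067). Its median was -0.070 without high-fat replicate 1, -0.10 without control replicate 2 and -0.096 without control replicate 3, and that of the fatty acid oxidation list was -0.0082 without high-fat replicate 1 and -0.0081 without control replicate 2. With an estimated correlation the adjusted p of the glycolysis list was 0.803. In the growth factor list 1 of 33 genes, Igf2, passed over all genes, and 5 were lower and 2 higher when adjusted over the list alone. Its median of 0.02 and its mean of -0.15 differed in sign, and its adjusted p was 0.699. The median and mean also differed in sign for lipogenesis, oxidative phosphorylation, MYC turnover, clock and erythroid genes.

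Markers of other cell types did not pass as lists. Medians were -0.49 for neutrophils and mast cells (adjusted p = 0.055), 0.12 for keratinocytes (adjusted p = 0.164), 0.08 for B cells (adjusted p = 0.372), -0.08 for Schwann cells (adjusted p = 0.564), 0.21 for endothelium (adjusted p = 0.611), -0.07 for T and NK cells (adjusted p = 0.732), 0.25 for macrophages (adjusted p = 0.955) and 0.07 for erythroid cells (adjusted p = 0.955). Leaving out 1 array moved the keratinocyte median between 0.080 and 0.24. It turned the sign of the median for B cells (-0.033 to 0.16), Schwann cells (-0.15 to 0.038), T and NK cells (-0.18 to 0.065) and erythroid cells (-0.031 to 0.11). Within the shared slide, where control replicate 1 is the sole control array, endothelial markers passed as higher with a median of 1.60 (adjusted p = 5.2e-13) and macrophage markers with 0.65 (adjusted p = 6.1e-07), but with an estimated correlation neither passed there (adjusted p = 0.634 for each). Without that control array the medians over the other 5 were -0.22 and -0.23 (adjusted p = 0.561 and 0.324). Endothelial list means varied widely within each diet, from -2.58 to -0.86 on the high-fat and from -2.91 to -1.50 on the control arrays. Leaving out 1 array moved the endothelial median between -0.28 and 0.59, and without high-fat replicate 1 the list passed (adjusted p = 0.0029, adjusted p = 0.796 with an estimated correlation). The neutrophil and mast cell list passed as lower in 11 of 26 alternatives and as higher in 0, and did not pass with an estimated correlation (adjusted p = 0.637). It passed with all 6 arrays under median scaling (adjusted p = 0.043), for example, and without high-fat replicate 2 (adjusted p = 0.019), without high-fat replicate 3 (adjusted p = 0.047) or without control replicate 2 (adjusted p = 0.0042), while its median was -0.23 without high-fat replicate 1 (adjusted p = 0.143) and -0.23 without control replicate 3 (adjusted p = 0.126). The keratinocyte list passed as higher in 3 alternatives, among them that without high-fat replicate 2 (adjusted p = 0.042, adjusted p = 0.607 with an estimated correlation). Within the macrophage list the galectin Lgals3 differed by -0.99 (SE 0.17). Milk genes (median 0.10, adjusted p = 0.699), endoplasmic reticulum stress genes (-0.05, adjusted p = 0.943), immediate early genes (-0.03, adjusted p = 0.955) and clock genes (-0.10, adjusted p = 0.955) did not pass either. In the 20 lists that did not pass, no member but Igf2 passed over all genes. When adjusted over the list alone, 2 keratinocyte genes were higher and 1 lower, 2 white adipocyte genes higher and 1 lower, 1 T and NK cell gene higher and 1 lower, 1 B cell gene higher, 2 Schwann cell genes lower and 1 macrophage gene lower. Apart from these and the fatty acid oxidation and growth factor genes above, the count was 0 in every such list.

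**Figure D3:**
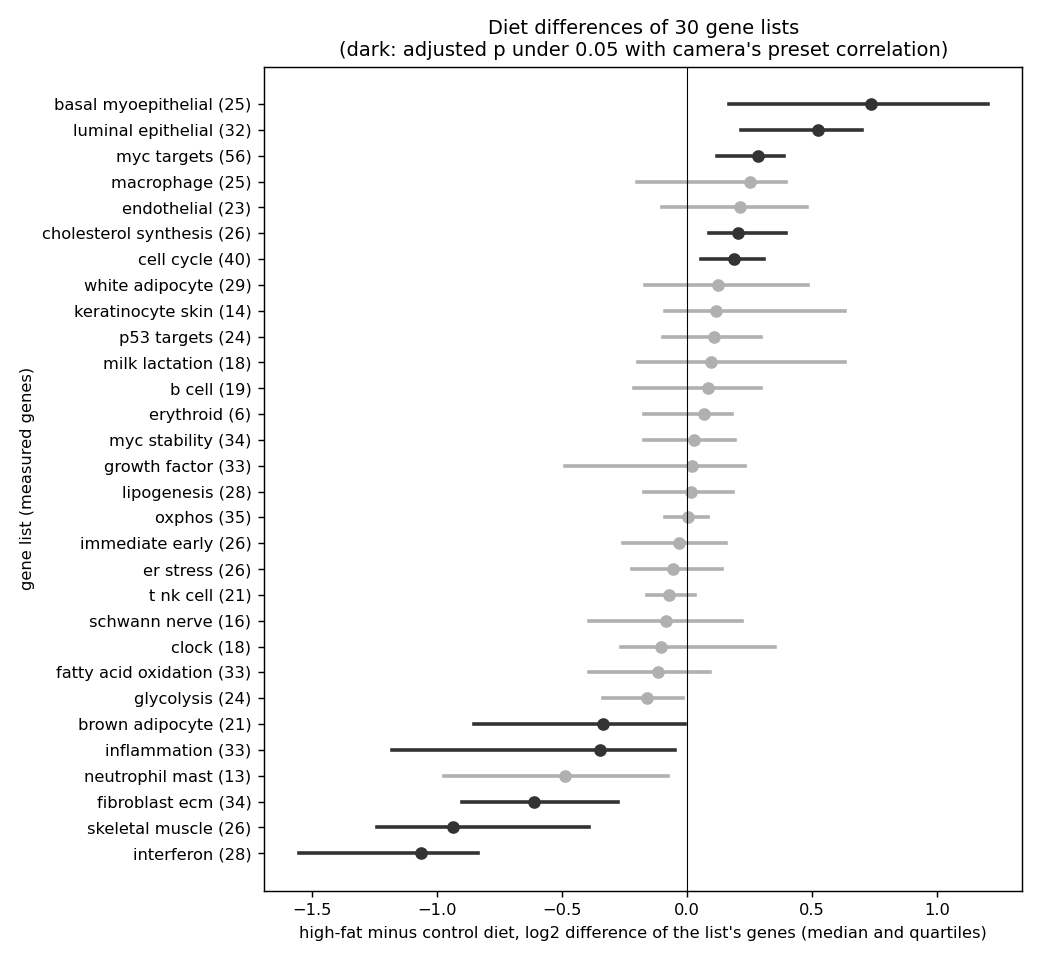
Median (point) and quartiles (bar) of the high-fat minus control log2 difference (x axis) over the measured genes of each of 30 lists (y axis, number of genes in parentheses). The 10 lists past an adjusted p of 0.05 with the preset correlation are dark and run from -1.07 for interferon genes to 0.74 for basal markers, and 0 of them passed with an estimated correlation.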

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

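The random slide block and the luminal covariate were chosen after seeing the data. The count of 4 genes was 0 with quantile normalization, 2 with median scaling, 0 with normexp and the 75th percentile, 7 with normexp and quantile normalization, 0 without the filter on dim probes, 7 with signal required on all 6 arrays, and 0 with slide as a block, the epithelial, the adipocyte or the luminal covariate. The 8 settings with all arrays that called 0 genes called 1101 to 5851 at an unadjusted p under 0.05. All calls under these scalings were lower after the high-fat diet, as in the main setting. Array weights, which gave control replicate 3 a weight of 4.70 and control replicate 1 one of 0.34, called 5409 genes, 2569 higher and 2840 lower; the cause was not tested. At an adjusted p under 0.10, 18 genes passed, 760 at an unadjusted p under 0.05 with a log2 difference of 1 or more, and 83 had diets apart by 1 or more. Leaving out 1 array gave 0 to 37. The remaining 6 alternatives gave 3 to 6 genes. The replicate block gave 0 genes (4044 at an unadjusted p under 0.05), 12 lists and 0.28 for the MYC targets. The deviations of arrays with the same number correlated at 0.33, -0.14 and 0.25, and those of arrays with different numbers at -0.38 to 0.23. With so few arrays per diet, these values cannot decide whether the numbers pair the samples. Scan date was not run as a block, as all scans fell on 1 day.

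Of the lists, 10 passed, against 0 with an estimated correlation, 2 with fry and 6 with the luminal covariate, and between 8 and 14 with the other alternatives, leaving out 1 array included (9 to 13). With the correlation estimated, 0 passed in any setting where it was estimated, and the lowest adjusted p was 0.070, without control replicate 3. That test has few degrees of freedom and low power in each of these settings. It was not estimated for lists cut to members of no other list. The random slide block was not run for lists. The MYC target median of 0.28 kept its call in 20 alternatives. It was 0.19 with normexp and the 75th percentile (adjusted p = 0.391), 0.025 with slide as a block, -0.39 with the epithelial covariate (adjusted p = 1.1e-07) and -0.025 with the luminal covariate, and lost its call at the same 0.28 with fry (adjusted p = 0.444) and with an estimated correlation. Leaving out 1 array moved it between 0.14 and 0.44. Over all alternatives its adjusted p ran from 6.0e-10 to 0.841, that of the skeletal muscle list from 3.8e-19 to 0.196, of the basal list from 1.0e-13 to 0.267, of Myl4 from 0.013 to 0.846 and of Igf2 from 0.013 to 0.939. The Trp53 difference stayed uncalled in all 24 alternatives, but its sign turned in 5: it was -0.46 with the epithelial covariate, -0.22 with the luminal covariate and -0.15 with slide as a block, and lay between -0.084 and 0.19 on leaving out 1 array. Endothelial and macrophage lists passed as higher with slide as a block (1.60 and 0.65) and with the epithelial covariate (1.69 and 1.04) but as lower with the adipocyte covariate (-0.73 and -0.47).

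Directions turned, with a call on either side, in these cases. The epithelial covariate, which itself differs between the diets, turned cell cycle (-0.26), lipogenesis (-0.31), cholesterol (-0.32), glycolysis (0.27), interferon (0.60), fibroblast (1.23), immediate early (0.20) and endoplasmic reticulum stress genes (0.28). The luminal covariate turned cholesterol (-0.014) and fibroblast genes (0.098), and slide as a block cell cycle (-0.022), cholesterol (-0.062) and fibroblast genes (0.091). The adipocyte covariate turned macrophage (-0.47) and endothelial genes (-0.73). Normexp with the 75th percentile put the median of all genes at 0.27, and relative to that Igf2 (0.13) lay at -0.14, skeletal muscle (0.13) at -0.14, brown adipocyte (0.16) at -0.10 and oxidative phosphorylation (-0.12) at -0.39; the cause was not tested. A covariate made of a list's own genes does not test that list (luminal genes, -0.55 with the epithelial and -0.028 with the luminal one), and is not counted here. Over the 9 called lists other than MYC targets, 192 of 231 comparisons kept the call, 28 lost it and 11 turned. Over the 20 uncalled lists, 479 of 518 stayed uncalled, 62 of them with the sign changed, 32 gained a call on the same side and 7 on the other. Among the named genes 124 comparisons gained a call, 108 of them with array weights, and 56 lost one. Uncalled values changed sign, without a call, 68 times for named genes.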

Other observations

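All weighing tests below other than the counts over splits were chosen after the values were seen. The labels give whole glands as the source and epithelial cells in the descriptions. Of some markers of fat cells and leukocytes, Adipoq lay between 0.62% and 1.87% of the 75th percentile of its array, Plin1 between 1.18% and 1.72%, Lep between 1.54% and 2.41% and the leukocyte antigen Ptprc between 1.51% and 2.59%. The B-cell gene Cd79a lay between 0.58% and 1.14%. The luminal keratin Krt18 was well above background on all 6 arrays, at 8.08 ± 0.44 under high-fat and 7.57 ± 0.32 under control diet (SD, n = 3 each), as was Vim, a filament protein of mesenchymal and cultured cells, at 6.39 ± 0.03 and 6.30 ± 0.21 (SD, n = 3 each). Of the milk genes, Csn2 was well above background on 0 arrays and Wap and Csn1s1 on 1 each. Lalba was so on all 6, between 12.2% and 15.4% of the 75th percentile of its array. These markers were chosen after their levels were seen, so they do not stand for all genes of those cells. The white adipocyte list, fixed beforehand, had means of -2.84 ± 0.14 under high-fat and -3.03 ± 0.19 under control diet (SD, n = 3 each). Levels of different probes are not comparable with each other. These values therefore do not settle whether whole glands or epithelial cells were hybridised.

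Over the 10 splits of the 6 arrays into 3 and 3, the diets gave 4 genes and the highest other split 0, so 1 split reached that count. The diets gave 10 lists past the preset test, the highest other split 14, and 3 splits reached 10 or more. With 10 splits the share cannot fall below 0.1. At an unadjusted p under 0.05 the diets gave 3129 genes, the split of high-fat replicates 1 and 2 with control replicate 1 against the other 3 arrays gave 5860, and the remaining 8 splits gave 202 to 1234.

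Muscle genes were lower after the high-fat diet with camera's preset correlation and with fry (adjusted p = 0.012) but not with an estimated correlation (adjusted p = 0.196). Adult muscle fibres carried over into control glands would bring their abundant transcripts, but 8 measured ones (Acta1, Atp2a1, Ckm, Mb, Mylpf, Pvalb, Pygm and Tcap) had a median log2 difference of -0.18 (SE 0.24 from resampling the genes), against -0.94 for the list, and 4 of the 8 were positive. Acta1, Mb, Atp2a1 and Pvalb were not lower (0.01 to 0.24), while Mylpf (-1.13), Tcap (-0.78), Ckm (-0.44) and Pygm (-0.38) were. Tnnc2, Tnnt3 and Myl1, which adult fibres also carry, were lower too. The 8 genes behind the median of -0.18 were picked after the values were seen and were split in sign. They cannot decide whether such fibres had a part. Against slide as the cause, the list's mean differed between slides within a diet by at most 0.13, against a diet difference of -0.95. Another candidate explanation left open is a difference in immature or differentiating muscle-like cells, or in a contractile programme of other cells, between the glands of the 2 diets, which was not tested.

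MYC targets were higher after the high-fat diet with camera's preset correlation but not with an estimated one (adjusted p = 0.690) or fry (adjusted p = 0.444), and their list mean followed the luminal list over the 6 arrays (Pearson r = 0.96, exact permutation p = 0.013, adjusted over 6 relations 0.025; Spearman rho = 0.89, exact permutation p = 0.033, adjusted 0.067). Without the 2 arrays farthest from the luminal median r was 0.94, and after removing each diet's mean it was 0.94. The 6 lists related to the luminal list here and below were picked among those already called by diet, and the permutations ignored diet. Their p-values therefore cannot separate a shared diet difference from a relation within diets. With the luminal mean as a covariate the diet difference of the MYC list mean went from 0.25 (SE 0.16) to 0.00347 (SE 0.08), which is consistent with a share of luminal cells, or a luminal state, that varies between glands of both diets. Slide is open too, since the list mean differed between slides by up to 0.27 within a diet, but high-fat replicates 2 and 3 also differed on 1 slide. An effect of diet on MYC activity within luminal cells stays untested.

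The fibroblast list followed the luminal list inversely (r = -0.99, exact permutation p = 0.0042, adjusted 0.013; rho = -0.94, exact permutation p = 0.017, adjusted 0.05), as did the interferon list (r = -0.94, exact permutation p = 0.0028, adjusted 0.013; rho = -0.94, exact permutation p = 0.017, adjusted 0.05). Without the same 2 arrays r was -0.996 and -0.81, and after removing each diet's mean -0.98 and -0.91. For cell cycle genes r was 0.92 (exact permutation p = 0.019, adjusted 0.029) and rho 0.77 (exact permutation p = 0.103, adjusted 0.154), with r = 0.76 without those arrays and 0.88 after removing each diet's mean, and for the muscle list r was -0.51 (exact permutation p = 0.268, adjusted 0.322) and rho -0.26 (exact permutation p = 0.658, adjusted 0.658), with r = 0.11 without them and 0.77 after removing each diet's mean, opposite in sign to the pooled r.

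Basal markers were higher after the high-fat diet with the preset correlation but not with an estimated one (adjusted p = 0.267) or fry (adjusted p = 0.051), and their list mean showed no relation to the luminal list that passed (r = 0.41, exact permutation p = 0.389, adjusted 0.389; rho = 0.49, exact permutation p = 0.356, adjusted 0.427; r = 0.00721 without the 2 farthest arrays and -0.66 after removing each diet's mean). With the luminal mean as a covariate the diet difference of the basal mean was 0.81 (SE 0.15), from 0.67 (SE 0.13) without it, which argues against the luminal share as its cause. Between slides within a diet the basal mean differed by at most 0.053, which argues against slide. A larger share or a stronger contractile and keratin programme of basal cells may remain as an explanation, and the data hold no cell counts to tell these apart.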
